A study of Rattus norvegicus with 12 samples.

How the data were processed

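RNA was measured in 12 libraries of rat anterior cingulate cortex, a frontal midline region, from 3 groups of 4: workers, parasites and home-cage controls. Per the labels' protocols, the animals were male Sprague-Dawley rats of about 8 to 10 weeks kept at 80 to 85% of normal weight. The region was dissected from 2 mm slices, all RNA had an integrity number above 8.5, and polyadenylated RNA from 1 µg of total RNA was made into libraries for an Illumina NovaSeq instrument. The deposited values are FPKM per gene (fragments scaled by transcript length and by the mapped fragments of the library), which the authors made with Cufflinks 2.1.1, per the submitters' processing notes. These notes also name TopHat, Cuffdiff and the genome build Rnor_5.0, in no stated order. No step that removed genes or samples before deposit is given in the sources used here.

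The table held 26689 genes, of which 37 rows on the mitochondrial chromosome held no value and 8177 were at 0 in all 12 libraries. Read counts were not used here, so the depth of a library is not known as a number of reads. For 235 short genes of low level, the ratio of each library to control replicate 1-1 was taken. Of these ratios, at least 41.7% lay within 0.05, on the log2 scale, of a whole number of doublings from the most common ratio. Taken from the most common ratio, the relative depth of the libraries ran from 1 to 1.45, a rough value, as many ratios lay elsewhere. FPKM summed to between 546636 and 593690 per library. Symbols and coordinates are those of the deposited table, and no reference genome was used.

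Each comparison was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), over the 12955 genes with a mean FPKM of at least 1 across all 12 libraries. All 12 libraries entered 1 linear model with a mean per group, variances were moderated with an intensity trend, and two-sided p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Because 1 is added before the logarithm, a log2 change understates the change of genes of low level. Errors of log2 changes are limma's moderated standard errors, and levels are the mean FPKM of 4 libraries with the SD. Each of 33 gene lists (pathways, cell type and region markers, protein complexes) with at least 3 measured members was tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the 33 lists. A list of mitochondrially encoded genes had 0 members with values. Of 903 list entries, 872 matched a gene symbol in the table. For each list the mean of log2(FPKM + 1) per library was also compared by a two-sided exact permutation test over the 70 relabelings of 4 against 4 libraries, whose smallest possible p is 0.0286. Exact permutation p-values are not adjusted over the 33 lists unless this is stated. Python 3.11.15 read the table and drew the figures.

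The design, the lists, the tests of genes and lists and the alternatives were written before the data were examined. The tests of the clock, of gene span, of the first number of the titles and by splits of the libraries were not part of that design. The rule for the genes named here was also written before the data were examined. By that rule, the 12 genes with the largest rise and the 12 with the largest fall past the threshold were taken per comparison, limited to plain gene symbols. Where fewer passed, the places were filled with the genes of smallest p. In addition, the 4 members of each list with the smallest p between workers and parasites may be named, and 12 genes of neuronal activity, dopamine, serotonin and stress signalling were named whatever their values. Other genes belong to a test described with them or are said to have been chosen after their values were seen. Some genes that meet the rule are not reported here.

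On simulated values for the 12955 genes with 200 genes changed, the worker and parasite comparison recovered 68% of 100 genes changed by 0.5 and 95% of 100 changed by 1 on the log2 scale, and called 11 of 12675 unchanged genes. For worker against control these were 62% and 90%, with 4 of 12676 unchanged genes called. For parasite against control they were 67% and 94%, with 14 of 12675 unchanged genes called. The ribosomal protein list of 80 genes, shifted by 0.1, was called in each of the 3 simulated comparisons, and 0 of the 32 other lists was. Most lists are smaller, and a shift of that size in them was not simulated. Genes in that simulation varied independently of each other, so it gives no rate of false list calls for correlated genes.

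The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, no intensity trend, array weights, and a model of only the groups compared. The numbers in the sample titles were also used as a block or averaged over, each library was left out in turn, and lists were tested with camera at an estimated correlation and with fry. The one-way p of fry asks whether the genes of a list move, on balance, in 1 direction, and its mixed p whether they change in either direction. A threshold of 0.1 was added after the data were seen. The labels state that the controls were 4 animals. They give no animal numbers for the tested rats, so that p-values of single genes and of the permutation tests measure the spread between these libraries. Camera sets the genes of a list against all other genes, so its p-values also rest on the preset correlation of 0.01. The estimated correlation was 0.618 for the ribosomal, 0.632 for the astrocyte, 0.49 for the microglia and 0.179 for the channel list.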

Results

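Transcript levels in the anterior cingulate cortex were compared between rats that had taken opposite roles in a shared feeding task. Per the labels' protocols, rats were first trained in 90 min sessions to press a lever for food, until they reached 100 presses a session. They were then tested in groups of 3, in which 1 rat came to do most of the pressing while the other 2 ate most of the food. A worker was a rat with more than 200 presses in a session that exceeded its 2 partners, the parasites, by more than 150 presses, in at least 3 sessions in a row. Brains were taken 18 to 19 h after that relation had formed. Home-cage controls had never entered the chamber. Each group held 4 libraries, whose FPKM summed to between 546636 and 593690, with 16134 to 16449 genes above 0. The relative depth estimated from the ratios of low values ran from 1 in control replicate 1-1 to 1.45 in control replicate 1-2.

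The question of the series is how workers differed from parasites. Ribosomal protein transcripts were higher in workers. The mean log2 level of 80 cytosolic ribosomal protein genes was 0.29 higher (SD 0.099 in workers and 0.10 in parasites, n = 4 libraries each), with 78 of the 80 members above the parasite mean. Examples are Rps27 at 672 ± 43.4 FPKM in workers against 508 ± 43.3 in parasites (SD, n = 4), Rps18 (log2 difference 0.42 ± 0.085, SE) and Rpl37 (0.40 ± 0.082). Markers of microglia, astrocytes and blood vessels were also higher, and transcripts of ion channels and of transmitter receptors were lower. Of the voltage-gated channel genes, which set the excitability of neurons, 34 of 38 were lower, with a mean difference of -0.20 (SD 0.070 and 0.059, n = 4 each). They include the sodium channel Scn1a (20.6 ± 1.37 FPKM in workers and 27.9 ± 2.93 in parasites), the potassium channel Kcna2 (-0.53 ± 0.12) and the calcium channel subunit Cacna2d3 (-0.27 ± 0.057).

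By camera, 14 of 33 lists differed between workers and parasites, 6 higher and 8 lower in workers. The ribosomal protein list had an adjusted p = 7.18e-26, and an adjusted p = 0.234 with an estimated correlation between its genes. The channel list had an adjusted p = 1.29e-08, and an adjusted p = 0.234 with an estimated correlation. In both lists the 4 worker libraries all lay on 1 side of the 4 parasite libraries (exact permutation p = 0.0286, the smallest possible). Adjusted over the 33 lists, that exact permutation p was 0.171 for both, the smallest of any list in this comparison. None of the 33 lists passed with an estimated correlation, fry called 11 in 1 direction, and camera called 8 with a mean FPKM of at least 5 as the filter. With that filter the interferon, meningeal, excitatory neuron, noradrenaline and acetylcholine receptor, serotonin and cholesterol synthesis lists lost their call. The serotonin call also ended without any filter and without worker replicate 1-1. Adjusted over the list alone, 63 ribosomal protein genes were higher and 12 channel genes lower, and 0 genes of either list passed over all genes tested. Both lists differed more between the libraries whose title begins with 1 than between those whose title begins with 2. The ribosomal difference was 0.43 in the first set and 0.15 in the second, and the channel difference was -0.28 and -0.12. The other 12 called lists had the same direction in both sets, for example 0.66 and 0.19 for microglia, 0.45 and 0.20 for astrocyte, 0.66 and 0.20 for endothelial, 0.45 and 0.12 for meningeal, 0.35 and 0.27 for interferon, -0.22 and -0.06 for glutamate receptor and -0.26 and -0.04 for excitatory neuron genes.

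All 19 microglia and macrophage markers were higher in workers, by a mean of 0.42 (SD 0.038 and 0.28, n = 4 each), and 15 passed adjusted over the list alone. Among them were the protease gene Ctss (0.61 ± 0.12, SE), Aif1 (0.48 ± 0.13) and Tmem119 (0.52 ± 0.16). The list had a camera adjusted p = 1.29e-08, an adjusted p = 0.234 with an estimated correlation, and an exact permutation p = 0.0286. All 21 astrocyte markers were higher, by a mean of 0.33 (SD 0.044 and 0.23), with 15 past the threshold adjusted over the list alone, such as the growth factor receptor Fgfr3 (0.41 ± 0.093) and the gap junction gene Gja1 (0.39 ± 0.098). That list had an adjusted p = 7.54e-09, an adjusted p = 0.3 with an estimated correlation, and an exact permutation p = 0.114. All 24 endothelial and pericyte markers were higher, by a mean of 0.43 (SD 0.12 and 0.22), and 18 passed adjusted over the list alone. The cadherin of endothelial junctions Cdh5 was at 0.54 ± 0.11 and the glucose transporter Slc2a1 at 0.50 ± 0.14. Their adjusted p was 1.34e-09, with an adjusted p = 0.234 with an estimated correlation. Meningeal and fibroblast markers were 0.28 higher (22 of 23 members, adjusted p = 0.000987, and adjusted p = 0.366 with an estimated correlation). Interferon and inflammation genes were 0.31 higher (18 of 21 members, adjusted p = 0.000654, and adjusted p = 0.326 with an estimated correlation), with Mx2 at 0.53 ± 0.11 and Isg15 at 0.82 ± 0.23. For the endothelial, meningeal and interferon lists the exact permutation p was 0.0571 each. Not all non-neuronal lists were higher in workers. Oligodendrocyte and myelin markers were at -0.07 (SD 0.19 and 0.31, camera adjusted p = 0.38), choroid plexus markers at 0.01 (adjusted p = 0.991) and blood markers at -0.32 (SD 0.19 and 0.38, adjusted p = 0.122).

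**Figure D1:**
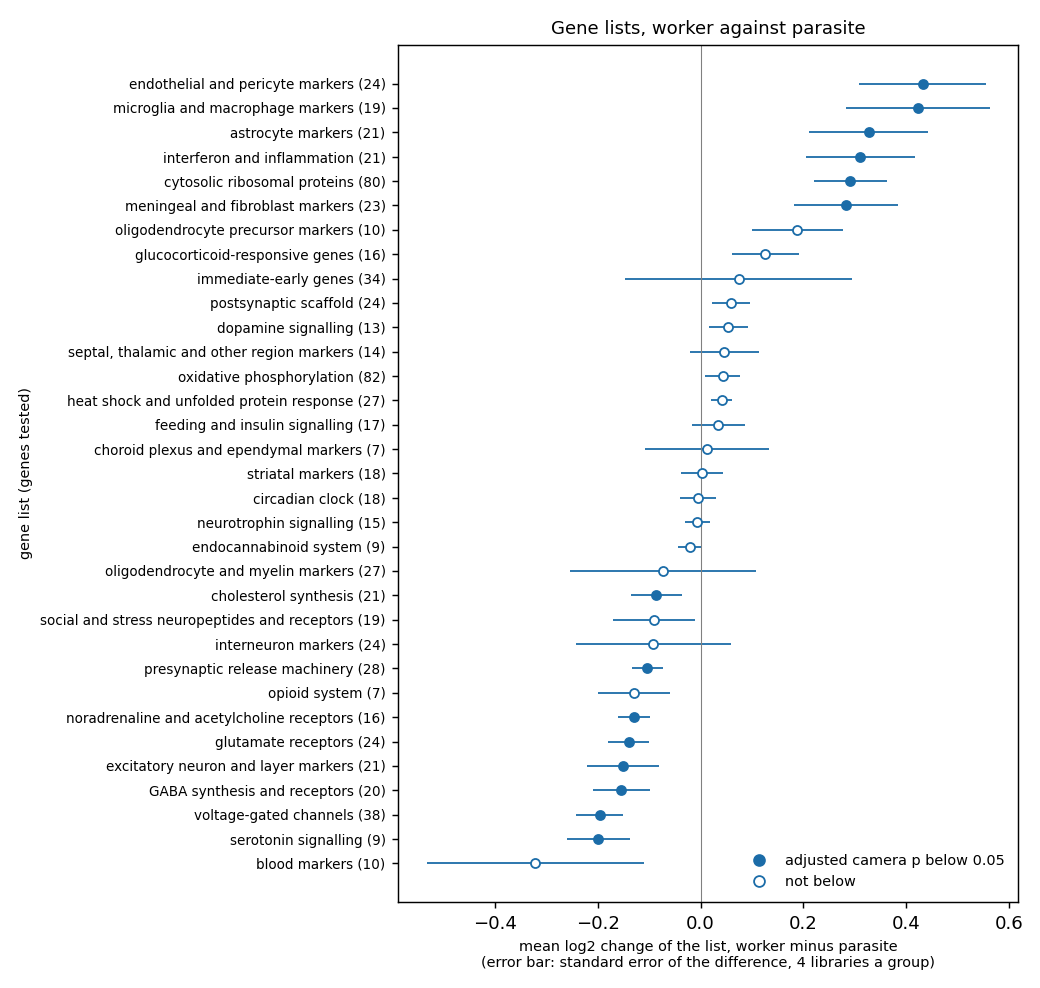
Mean log2 change of each of 33 gene lists, worker minus parasite, on the x axis in log2 units, with the standard error of the difference between 4 and 4 libraries as the bar and the number of genes tested in brackets. The endothelial list lies highest of the called lists at 0.43 and the voltage-gated channel list lies at -0.20; filled points mark an adjusted camera p below 0.05.

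Transcripts of synaptic genes were lower in workers in 3 further lists. In the glutamate receptor list 18 of 24 genes were lower (mean -0.14, 8 lower and 1 higher adjusted over the list alone, adjusted p = 0.00162, and adjusted p = 0.234 with an estimated correlation). Among them were the AMPA receptor subunit genes Gria4 (-0.31 ± 0.083, SE) and Gria2 (-0.24 ± 0.081), while Grin2c was at 0.52 ± 0.17. In the GABA list 14 of 20 were lower (mean -0.15, 4 adjusted over the list alone, adjusted p = 0.00972, and adjusted p = 0.234 with an estimated correlation). The receptor subunit gene Gabrb2 was at -0.48 ± 0.13. In the presynaptic release list 20 of 28 were lower (mean -0.10, 7 lower and 1 higher adjusted over the list alone, adjusted p = 0.00795, and adjusted p = 0.234 with an estimated correlation), including the calcium sensor Syt1 (-0.36 ± 0.091). The exact permutation p was 0.0571 for the glutamate receptor list, 0.0571 for the GABA list and 0.0286 for the presynaptic list. Neither the glutamate receptor list (-0.07, adjusted p = 0.352) nor the GABA list (-0.13, adjusted p = 0.129) was called after a trend of the change on gene span was subtracted. The other lists called lower were excitatory neuron and layer markers (-0.15, 17 of 21 lower, adjusted p = 0.0145), noradrenaline and acetylcholine receptors (-0.13, 12 of 16, adjusted p = 0.0146), serotonin signalling (-0.20, 8 of 9, adjusted p = 0.0265) and cholesterol synthesis (-0.09, 15 of 21, adjusted p = 0.0409). The cholesterol call was kept in 7 of the 12 models without 1 library. With an estimated correlation their adjusted p was 0.234, and 0.546 for cholesterol synthesis. Exact permutation p was 0.114 for excitatory neuron markers, 0.0286 for noradrenaline and acetylcholine receptors, 0.0571 for serotonin signalling and 0.2 for cholesterol synthesis. Postsynaptic scaffold genes had no common direction (12 of 24 higher, adjusted p = 0.569), and of them the scaffold genes Shank3 (0.42 ± 0.11), Shank1 (0.35 ± 0.099) and Dlg4 (0.27 ± 0.073) were higher in workers adjusted over the list alone.

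No single gene passed the threshold between workers and parasites. In limma 0 of 12955 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.0705, and 3143 genes (24.3%) had an unadjusted p under 0.05, against 648 expected by chance. Of these, 1689 were higher and 1454 lower in workers. The genes of smallest p, none of which passed, all had an adjusted p = 0.0705. Higher in workers were the ubiquitin ligase gene Neurl1 (252 ± 11.4 FPKM against 182 ± 25.1 in parasites, SD, n = 4), the calcium-binding protein gene S100a6 (11.4 ± 1.93 against 5.35 ± 1.65), and the thyroid hormone receptor Thra (282 ± 14.1 against 234 ± 3.67). So were the serine synthesis enzyme Phgdh (60.6 ± 6.42 against 41.8 ± 6.78), the lipid synthesis regulator Srebf1 (30.6 ± 1.74 against 23.9 ± 1.8), and the histone methyltransferase Ehmt2 (76.1 ± 3.83 against 60.0 ± 5.46). Mif4gd, Dusp26, Ltbp4, Gpld1 and Cnn3 were higher with log2 differences from 0.30 to 0.57. Lower in workers were the ephrin receptor Epha6 (9.89 ± 0.427 against 14.4 ± 1.5), the acetylcholine receptor chaperone Ric3 (12.1 ± 1.3 against 16.4 ± 0.58), and the splicing regulator Nova1 (19.8 ± 1.74 against 25.9 ± 1.95). So was the secreted synaptic protein gene Lgi1 (59.8 ± 4.62 against 77.5 ± 7.58). Ntng1, Chm, Clvs1, Btbd8 and Immt were lower with log2 differences from -0.59 to -0.23. The count of 0 rested on the libraries and weights used. It was 1225 without parasite replicate 2-2, 232 without control replicate 1-1, 3 without parasite replicate 1-2, 1064 with array weights, 1 in a model of these 8 libraries alone and 3 with the libraries of a group that share a first number averaged.

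Among the genes named whatever their values, Fos, Arc, Egr1, Npas4, Bdnf, Crh, Drd1, Drd2 and Fkbp5 had adjusted p-values from 0.425 to 0.978 between workers and parasites. The serotonin receptor Htr2a was at 21.2 ± 3.02 FPKM in workers and 26.8 ± 3.24 in parasites (SD, n = 4; adjusted p = 0.118). The oxytocin receptor Oxtr (0.117 ± 0.0931 FPKM in workers, 0.197 ± 0.11 in parasites, 0.205 ± 0.297 in controls) and the vasopressin receptor Avpr1a (0.512 ± 0.339, 0.424 ± 0.172 and 0.269 ± 0.116) lay below the filter on low values and were not tested. Dopamine signalling (mean 0.05, adjusted p = 0.394), social and stress neuropeptides (-0.09, adjusted p = 0.125), opioid (-0.13, adjusted p = 0.209), endocannabinoid (-0.02, adjusted p = 0.611), feeding and insulin (0.03, adjusted p = 0.991), neurotrophin (-0.01, adjusted p = 0.534), glucocorticoid-responsive (0.13, adjusted p = 0.408), circadian clock (-0.01, adjusted p = 0.991), heat shock (0.04, adjusted p = 0.991), interneuron (-0.09, adjusted p = 0.215), oligodendrocyte precursor (0.19, adjusted p = 0.0542), oxidative phosphorylation (0.04, adjusted p = 0.332), immediate-early (0.07, adjusted p = 0.603), striatal (0.00, adjusted p = 0.991) and septal or thalamic lists (0.05, adjusted p = 0.603) did not pass with camera between workers and parasites. Some of these lists passed by fry's mixed p, which tests for changes in either direction. Adjusted mixed p was 0.000336 for the septal and thalamic markers, 0.00995 for neurotrophin genes, 0.014 for the social and stress neuropeptides and for the postsynaptic scaffold, 0.0147 for heat shock and 0.0421 for oligodendrocyte precursors. Among the septal and thalamic markers, adjusted over the list alone, Zic2 (0.51 ± 0.14, SE) and Zic5 (0.49 ± 0.15) were higher and Ntng1 (-0.59 ± 0.12) lower in workers.

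Workers were compared with home-cage controls to show how the tested rats stood against rats without the task. Immediate-early genes, which neurons transcribe within minutes of activity, were lower in workers. All 34 measured members lay below the control mean, the mean log2 difference was -0.85 (SD 0.35 in workers and 0.17 in controls, n = 4 libraries each), and 28 passed adjusted over the list alone. The transcription factor genes Fosb (6.03 ± 1.35 FPKM against 18.9 ± 5.11 in controls, SD, n = 4; log2 change -1.48 ± 0.19, SE; adjusted p = 0.0437) and Egr4 (35.2 ± 5.55 against 82.5 ± 19; -1.19 ± 0.16; adjusted p = 0.0437) fell past the threshold over all genes. Fosb lies on chromosome 1 from 81481174 to 81487900 and Egr4 on chromosome 4 from 181870041 to 181872503 in Rnor_5.0, both on the minus strand. Not past it were Nr4a2 (-1.10 ± 0.17) and Jun (-0.44 ± 0.069), each with an adjusted p = 0.0812, Egr1 (-1.06 ± 0.18, adjusted p = 0.139), and Egr2 (-1.60 ± 0.33, adjusted p = 0.159). Nor were Fos (15.5 ± 8.31 against 57.0 ± 19.4 FPKM, adjusted p = 0.174), Arc (79.2 ± 53.9 against 205 ± 73.7, adjusted p = 0.387), Npas4 (-1.48 ± 0.64, adjusted p = 0.433) and Bdnf (-0.61 ± 0.21, adjusted p = 0.379). With both numbers of the title as a block Nr4a2, Jun, Egr1, Fos, Arc and Npas4 passed, and with the first number alone Nr4a2, Jun and Fos. Egr2 and Bdnf passed with neither block, and none of these genes passed with libraries that share a first number averaged.

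**Figure D2:**
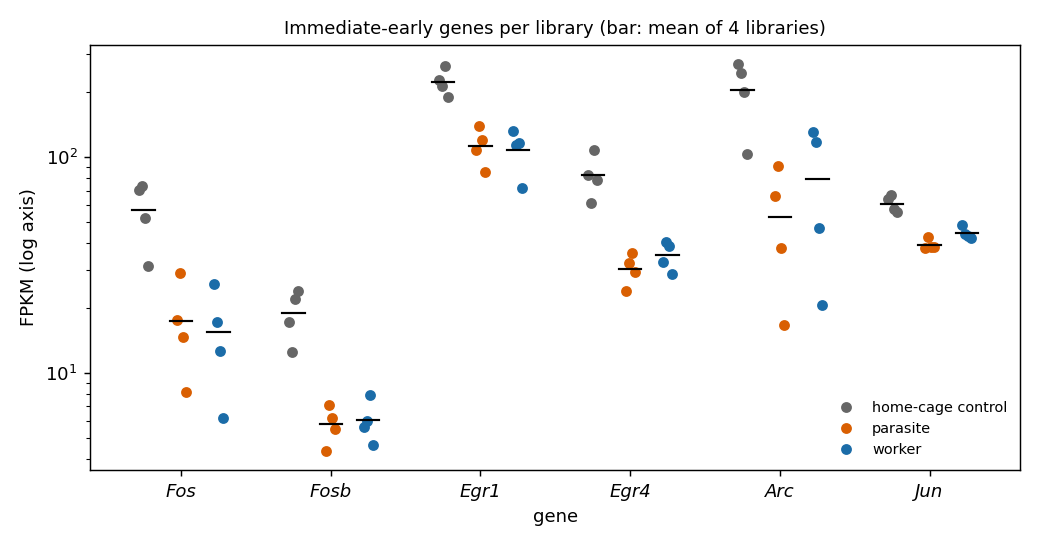
FPKM of 6 immediate-early genes on a log axis, 1 point per library, with a bar at the mean of 4 libraries. Fosb averages 18.9 FPKM in controls, 5.77 in parasites and 6.03 in workers, and the 4 control libraries of Fosb and Egr4 lie above all worker and parasite libraries.

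The immediate-early list had a camera adjusted p = 2.21e-25, an adjusted p = 0.0942 with an estimated correlation, and an exact permutation p = 0.0286 (0.118 adjusted over the 33 lists). Within the libraries whose title begins with 1 the difference was -0.66, and within those whose title begins with 2 it was -1.05. Camera called 17 of 33 lists between workers and controls, 8 higher and 9 lower, and 0 with an estimated correlation, while fry called 1, the immediate-early list. Heat shock and unfolded protein response genes were lower (25 of 27 members, mean -0.20, 16 past the threshold adjusted over the list alone and 0 over all genes tested; adjusted p = 8.73e-12, and adjusted p = 0.276 with an estimated correlation). Their difference was -0.06 within the first set of titles and -0.34 within the second. Glucocorticoid-responsive genes were lower in 12 of 16 cases (mean -0.23, 5 adjusted over the list alone and 0 over all genes tested, adjusted p = 0.000703, and adjusted p = 0.276 with an estimated correlation), among them Tsc22d3 (38.5 ± 2.72 against 54.6 ± 6.72 FPKM in controls, SD, n = 4; adjusted p = 0.159), while Fkbp5 was at 18.6 ± 1.76 against 18.1 ± 2.85 FPKM. The list differed by -0.08 within the first set of titles and by -0.39 within the second.

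Microglia (0.36, 19 of 19 higher), astrocyte (0.25, 21 of 21), endothelial (0.22, 22 of 24) and oligodendrocyte precursor markers (0.23, 8 of 10) and ribosomal protein genes (0.11, 74 of 80) were higher in workers than in controls. Their camera adjusted p-values were 1.64e-11, 4.23e-10, 5.15e-06, 0.000464 and 4.23e-10 in that order, and with an estimated correlation the adjusted p was 0.276, 0.309, 0.391, 0.281 and 0.558. Exact permutation tests gave p = 0.0286 for the microglia, astrocyte and precursor lists, p = 0.0857 for the endothelial list and p = 0.229 for the ribosomal list. Also called were postsynaptic scaffold genes (0.07, adjusted p = 0.019), oxidative phosphorylation (0.04, adjusted p = 0.019) and meningeal markers (0.10, adjusted p = 0.0477), higher. Without 1 library the meningeal call was kept in 5 of 12 models (0.034 to 0.166 over these models). The calls of oxidative phosphorylation (0.006 to 0.072) and of the postsynaptic scaffold (0.052 to 0.094) were kept in 9. Lower were excitatory neuron markers (-0.18, adjusted p = 0.019), social and stress neuropeptides (-0.15, adjusted p = 0.0115), noradrenaline and acetylcholine receptors (-0.10, adjusted p = 0.0247), voltage-gated channels (-0.07, adjusted p = 0.0302), cholesterol synthesis (-0.09, adjusted p = 0.00329) and blood markers (-0.33, adjusted p = 0.019). The excitatory neuron list shares Nr4a2 (-1.10) with the immediate-early list, and its median change was -0.107. The channel call was kept in 7 of the 12 models without 1 library (-0.102 to -0.038 over these models). Those of blood markers (-0.443 to -0.199) and of noradrenaline and acetylcholine receptors (-0.125 to -0.094) were kept in 9. The ribosomal difference kept its call but was 0.061 without control replicate 2-1 and 0.179 without control replicate 1-1. With an estimated correlation the adjusted p of these 9 lists lay between 0.276 and 0.727. Their exact permutation p ran from 0.0286 (excitatory neuron markers, and noradrenaline and acetylcholine receptors) to 0.486 (oxidative phosphorylation), and was 0.257 for channels. The corticotropin-releasing hormone gene Crh (5.21 ± 0.871 against 7.96 ± 0.315 FPKM, adjusted p = 0.348) and the neuropeptide gene Adcyap1 (18.1 ± 3.44 against 26.9 ± 2.31, adjusted p = 0.159) were among the genes below controls that did not pass.

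In limma 2 of 12955 genes passed between workers and controls, both lower, and 1466 had an unadjusted p under 0.05. The genes of smallest p above the controls, all with an adjusted p of 0.159 to 0.17, were Dbp, Rps6ka4, Phkg1, Notum, Naaa, Gpr146, Nr1d1, Zfp867, Aldh3b2, Fads6, the microglial receptor gene Gpr34 and Nrarp, with log2 differences from 0.32 to 0.71. Below the controls Btbd8 (-0.40 ± 0.068), Otud1 (-0.59 ± 0.10), Jkamp (-0.24 ± 0.044) and Tmem178a (-0.30 ± 0.061) had adjusted p-values from 0.139 to 0.159. Both calls ended with median-of-ratios scaling, without the filter on low values, without the intensity trend, in a model of these 8 libraries alone and with libraries that share a first number averaged, and Egr4 ended with quantile normalization. Without 1 library the count was 5 (control replicate 1-2), 2 (parasite replicate 1-1), 1 (worker replicate 2-1) or 0 (each of the other 9), and 11 lists were called without worker replicate 1-2.

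Parasites were compared with the same controls. Immediate-early genes were again lower: 33 of 34 members lay below the control mean, by a mean of -0.93 (SD 0.26 in parasites and 0.17 in controls, n = 4 each), and 26 passed adjusted over the list alone, 3 of them over all genes tested. Over all genes Fosb fell by 1.53 on the log2 scale (5.77 ± 1.15 against 18.9 ± 5.11 FPKM, SD, n = 4; adjusted p = 0.0088), Egr4 fell by 1.40 (30.3 ± 5.06 against 82.5 ± 19; adjusted p = 0.00775) and Jun fell by 0.62 (39.4 ± 2.32 against 61.0 ± 5.33; adjusted p = 0.00775). Also past the threshold and lower were the glucocorticoid-induced leucine zipper gene Tsc22d3 (34.0 ± 3.38 against 54.6 ± 6.72; adjusted p = 0.015), the stress response factor Ddit3 (17.3 ± 1.04 against 25.1 ± 1.78; adjusted p = 0.0154), Rsrp1 (70.3 ± 1.95 against 131 ± 24.8; adjusted p = 0.0137) and the polyadenylation factor Cstf2 (18.2 ± 0.726 against 25.3 ± 1.53; adjusted p = 0.0128). The fatty acid desaturase family gene Fads6 rose (21.3 ± 0.936 against 15.7 ± 0.808; log2 change 0.42 ± 0.068, SE; adjusted p = 0.0498), a call kept in 2 of the 12 models without 1 library. It ended without the filter on low values, without the intensity trend, in a model of these 8 libraries alone and with libraries averaged.

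The other 2 genes that rose in parasites carry no plain symbol and are named after their values were seen. LOC316935, on chromosome 16 from 43725 to 45840 in Rnor_5.0, was at 12.3 ± 3.91 FPKM against 3.69 ± 0.652 in controls and 4.61 ± 0.271 in workers (SD, n = 4; adjusted p = 0.00864). LOC100912852, on chromosome 9 from 11366446 to 11368305, was at 415 ± 70.4 against 265 ± 12.1 and 280 ± 13.1 (adjusted p = 0.0314), and its call was kept in 5 of the 12 models without 1 library. Whether near-identical gene copies share reads with these rows is not known from the table, so their values are uncertain. Jun lies on chromosome 5 from 117958961 to 117959965, Tsc22d3 on chromosome 3 from 52711812 to 52715431, Ddit3 on chromosome 7 from 70754398 to 70759220, Rsrp1 on chromosome 5 from 157029893 to 157033632, Cstf2 on the X chromosome from 104716668 to 104742710 and Fads6 on chromosome 10 from 104447218 to 104462044.

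Camera called 9 of 33 lists between parasites and controls, 3 higher and 6 lower, and 0 with an estimated correlation, while fry called 3. The immediate-early list had an adjusted p = 2.73e-24, an adjusted p = 0.108 with an estimated correlation, and an exact permutation p = 0.0286 (0.236 adjusted over the 33 lists). Its difference was -0.86 within the first set of titles and -0.99 within the second. Glucocorticoid-responsive genes (13 of 16 lower, mean -0.36, 8 past the threshold adjusted over the list alone and 1 over all genes tested) had an adjusted p = 0.000122 and an adjusted p = 0.332 with an estimated correlation. Heat shock and unfolded protein response genes (24 of 27 lower, mean -0.24, 15 adjusted over the list alone and 1 over all genes tested) had an adjusted p = 1.9e-10 and an adjusted p = 0.395 with an estimated correlation. Both gave an exact permutation p = 0.0286 (0.236 adjusted over the 33 lists). The heat shock difference was -0.117 within the first set of titles and -0.366 within the second, and the glucocorticoid difference -0.335 and -0.384. Ribosomal protein genes were lower than in controls (77 of 80 members, mean -0.18, SD 0.10 in parasites and 0.15 in controls), with an adjusted p = 7.18e-16 and an adjusted p = 0.451 with an estimated correlation. Their difference was -0.34 within the first set of titles and -0.02 within the second. Endothelial markers (-0.21, adjusted p = 0.000784) and interferon genes (-0.24, adjusted p = 0.000784) were lower, with an adjusted p = 0.637 and an adjusted p = 0.451 with an estimated correlation. The endothelial difference was -0.43 within the first set of titles and 0.004 within the second. Voltage-gated channels (0.13, 34 of 38 higher, adjusted p = 5.68e-07), glutamate receptors (0.09, 20 of 24, adjusted p = 0.00251) and the GABA list (0.09, 17 of 20, adjusted p = 0.0105) were higher. With an estimated correlation their adjusted p was 0.395, 0.436 and 0.42. Their exact permutation p was 0.0286, 0.0857 and 0.171. Within the second set of titles these 3 differences were 0.052, 0.009 and 0.016. Microglia markers (-0.07, adjusted p = 0.598) and astrocyte markers (-0.08, adjusted p = 0.15) did not pass.

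**Figure D3:**
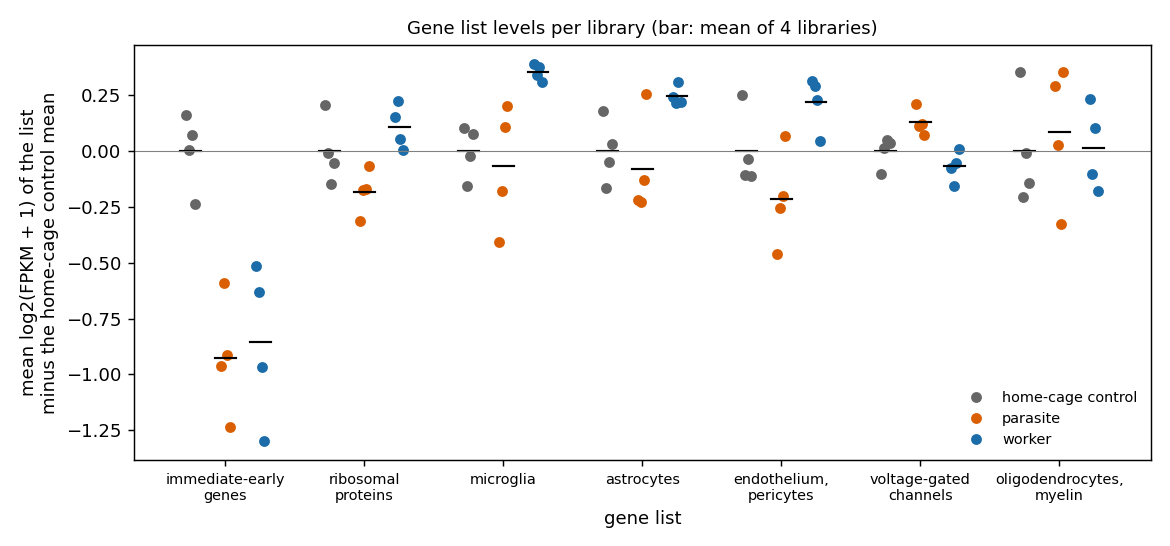
Mean log2(FPKM + 1) of 7 gene lists per library, minus the mean of the 4 home-cage controls, with a bar at the mean of 4 libraries. The immediate-early list lies 0.85 below the controls in workers and 0.93 below them in parasites, and all worker libraries lie above all parasite libraries for ribosomal proteins and microglia.

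In limma 10 of 12955 genes passed between parasites and controls, 3 higher and 7 lower, and 1764 had an unadjusted p under 0.05. Not past the threshold, with adjusted p-values from 0.103 to 0.124, were the clock gene Ciart (20.5 ± 3.74 against 13.1 ± 1.53 FPKM, SD, n = 4), Ppp3cc, Large, Dnajc30, Clcc1, Nova1, Zfp867, the kinase Camk4, Adam23 and Tfe3 above the controls. Below the controls and not past it were Egr1, Egr2, Fxyd5, the neurotrophic factor gene Nrtn and Sh3bp1. Fos (17.4 ± 8.77 against 57.0 ± 19.4 FPKM, adjusted p = 0.13) and Arc (53.0 ± 32.6 against 205 ± 73.7, adjusted p = 0.181) also did not pass. Fos and Arc passed with the first number or both numbers of the title as a block, and Egr1 with both numbers only. Egr2 passed with neither block, and none of these genes passed with libraries that share a first number averaged. Crh, as in workers, was below the controls and did not pass (5.47 ± 1.76 against 7.96 ± 0.315 FPKM, adjusted p = 0.236). Nor did Npas4 (-1.45 ± 0.64, SE, adjusted p = 0.353), Bdnf (-0.54 ± 0.215, adjusted p = 0.31), Htr2a (0.31 ± 0.12, adjusted p = 0.293) and Fkbp5 (-0.13 ± 0.13, adjusted p = 0.692). With both numbers of the title as a block Npas4 passed. In a model of these 8 libraries alone 0 genes passed (1558 at an unadjusted p under 0.05), and 4 passed with libraries that share a first number averaged. Leaving out 1 library gave 4 genes without parasite replicate 1-1, 5 without control replicate 2-1, 6 without control replicate 2-2 and 29 without control replicate 1-2. Fosb, Egr4, Jun and LOC316935 passed in all 12 such models, and 14 lists were called without parasite replicate 2-2.

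Both comparisons used the same 4 control libraries. Fosb and Egr4 passed and were lower in both, so 2 calls were shared. In 100 simulations of unchanged groups the mean number of shared calls was 0, and independent lists of these sizes would share 0.00108 lower genes. Unchanged groups are expected to give few calls to share, and the second value ignores the shared controls. Neither value tests whether the controls account for the 2 shared calls. With the controls split 2 and 2, in 6 ways, 0 calls were shared, but each comparison then had only 2 controls. Over all genes the log2 changes of workers and parasites against the controls had a correlation of 0.345, against 0.51 (SD 0.049) in the simulated unchanged groups. The covariance was 0.0151, within the spread of the simulated 0.0137 (SD 0.0021). With the controls split the correlation lay between -0.145 and 0.133 and the covariance between -0.00994 and 0.00693. Genes are not independent replicates.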

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

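The tests of cell mix and of transcript length, those of the immediate-early list, and the splits for genes at an unadjusted p against the controls, were chosen only after those values were seen. In 288 groups of 4 libraries (named genes, called lists and library measures), 14 had 1 library far from the other 3, by a gap that took up most of the range of the 4, and chance gives about 14.4. With that gap as a share of the range, they were Thra in controls (0.842, replicate 1-1 high) and in workers (0.945, replicate 1-2 high), Dusp26 in controls (0.858, 2-1 low), Ehmt2 in workers (0.914, 2-2 low), Phgdh in parasites (0.868, 2-2 high), Cnn3 in controls (0.869, 1-2 low) and in workers (0.92, 1-1 high), Phkg1 in parasites (0.856, 1-1 low), Jun in parasites (0.877, 1-2 high), Ppp3cc in workers (0.951, 1-2 low), Dnajc30 in parasites (0.865, 1-2 high) and Ddit3 in workers (0.844, 2-2 low). The same holds for 2 list means in parasites, cholesterol synthesis (0.838, 2-1 high) and oligodendrocyte precursor markers (0.848, 2-2 high).

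Between workers and parasites, camera called ribosomal protein, microglia, astrocyte and vascular lists higher and channel and receptor lists lower in workers. With an estimated correlation 0 of the 33 lists passed. A lower share of neurons would raise the markers of every other cell type alike. The oligodendrocyte list lay 0.47 below the mean of the astrocyte, microglia and endothelial lists (difference -0.468, SD 0.142 in workers and 0.371 in parasites, n = 4 each, exact permutation p = 0.0857). That p did not reach 0.05 in a test chosen after the values were seen, so it does not decide. A lower share of neurons, more RNA from the cell types that rose, or a change within them all stay open. A bias toward short transcripts would move the transcripts of oxidative phosphorylation, taken as short, too. These were at 0.043, and the ribosomal list exceeded them by 0.248 (SD 0.058 and 0.085). Transcript lengths were not available here, and gene span is not transcript length, so a length bias is not excluded. The change fell with gene span over all genes (Spearman's rho -0.204, over genes, which are not independent), and subtracting that trend left 0.23 of the ribosomal 0.291 and -0.161 of the channel -0.196, while of the 14 called lists 12 were called again, the glutamate receptor (-0.14 before, -0.066 after) and GABA lists (-0.154, -0.126) not, so for these a trend with span stays open; the postsynaptic scaffold and oligodendrocyte precursor lists became called (adjusted p = 0.0492 and 0.0384). At least 12 of the 14 called lists stayed called without any 1 worker or parasite library, but 5 of the 35 splits of these 8 libraries gave at least 14 lists (up to 18), so chance cannot be excluded for their number and a tie to the social role stays an untested hypothesis.

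For single genes between workers and parasites the real count was 0, which each of the 35 splits reaches by construction, so these splits decide nothing there (highest other 2). For genes at an unadjusted p under 0.05, 1 of the 35 splits, the real one, reached 3143, and the highest other count was 2905. First of 35 is the most extreme rank these splits can give, and it was not adjusted over the several counts compared. It argues against chance for that count but does not exclude it. Against the controls the real split did not rank first: 4 of 35 splits reached the 1466 of workers (highest other 2356) and 2 of 35 the 1764 of parasites (highest other 2255). Between workers and controls 2 of 35 splits gave at least 2 genes (highest other 5), so chance cannot be excluded by these splits. The only other split to reach 2 was the one by the first number of the titles, by which the libraries also differed, and with that number in the model 5 genes passed between workers and controls (Egr4, Fos, Fosb, Jun and Nr4a2, all lower). None of these 5 passed with the libraries that share that number averaged, where the 1 call was another gene, higher. Only 1 of the 35, the real split, gave 17 lists (highest other 14). With the same limits this argues against chance without excluding it, and 0 of these lists passed with an estimated correlation. Between parasites and controls 2 of 35 splits gave at least 10 genes (highest other 11) and 20 gave at least 9 lists (highest other 16), so chance can be excluded for neither count.

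Immediate-early genes were lower than in home-cage controls in workers and in parasites. By camera with an estimated correlation the list had an adjusted p = 0.0942 in workers and 0.108 in parasites. Each group held 2 libraries of each first number, so the differences within these sets (the smallest was -0.656) do not test whether the sets play a part. A lower share of excitatory neurons would lower their markers by a like amount, but these were at most -0.176 lower (with Nr4a2, which is in both lists, included), against -0.853 in workers and -0.927 in parasites for the immediate-early list. Time of death, handling before death and the recent history of the control rats may each account for it, as may the task, and none of these was tested here.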

How the results depend on the processing

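The threshold of 0.1 was chosen after seeing the data. The count of genes between workers and parasites, 0, became 1064 with array weights, 1 in a model of only the 2 groups compared, 3 with libraries sharing the first number averaged and 1237 at a threshold of 0.1, and ran from 0 to 1225 without 1 library. It was 0 with each pseudocount, filter and scaling. Between workers and controls the count of 2 became 1 without the filter on low values, 0 with median-of-ratios scaling, 1 with quantile normalization, 0 without the intensity trend, 4 with array weights, 0 in a model of only the 2 groups, 1 with libraries averaged and 4 at a threshold of 0.1, and ran from 0 to 5 without 1 library. Between parasites and controls the count of 10 became 0 in a model of only the 2 groups, 4 with libraries averaged, 8 without the intensity trend, 9 without the filter, 11 with a mean FPKM of at least 5 or with quantile normalization, 14 with array weights and 12 at a threshold of 0.1, and ran from 4 to 29 without 1 library. The cause of these changes was not tested. The 2 calls shared by both comparisons, Fosb and Egr4, both ended in workers without the filter, where the 1 shared call was another gene. Shared calls were 3 with array weights (these and Tsc22d3), 0 with median-of-ratios scaling, 1 with quantile normalization, 0 without the trend, 0 in models of only the 2 groups and 0 with libraries averaged, and ran from 0 to 3 without 1 library.

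Called lists between workers and parasites, 14, became 8 with a mean FPKM of at least 5 and 0 with camera at an estimated correlation, and ran from 12 to 16 without 1 library. The 17 lists between workers and controls became 0 with an estimated correlation and 1 with fry, and ran from 11 to 17. The 9 between parasites and controls became 0 with an estimated correlation and 3 with fry, and ran from 8 to 14. The lists that lost their call most often without 1 library were, against controls, meningeal (kept in 5 of 12) and channel genes (7) in workers, and between workers and parasites cholesterol synthesis (7). Cholesterol synthesis also ended with a mean FPKM of at least 5, with quantile normalization and in a model of only the 2 groups. The meningeal call ended without the filter, with a mean FPKM of at least 5, with both scalings and with the first number as a block. Without 1 library, these called lists kept their direction but moved by over 1.5 times. In workers against controls they were ribosomal (0.11 to between 0.061 and 0.179), blood (-0.327 to -0.199), meningeal (0.105 to between 0.034 and 0.166), oxidative phosphorylation (0.036 to between 0.006 and 0.072), channel (-0.068 to -0.038) and social and stress neuropeptide genes (-0.155 to -0.094). In parasites against controls they were ribosomal (-0.181 to -0.112), glutamate receptor (0.094 to 0.06) and endothelial genes (-0.213 to -0.129). The cause was not tested. No called list changed direction under any of these alternatives. No scaling moved the median log2 change of all genes beyond 0.012 in size in any comparison.

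Genes whose small difference turned direction, none past the threshold in these models, were Crh between workers and parasites (0.02 with array weights) and Drd1 between parasites and controls (0.022 with quantile normalization). The cause was not tested. Without 1 library, the differences between workers and parasites ran from -0.546 to 0.381 for Npas4, -0.202 to 0.124 for Crh, -0.159 to 0.018 for Bdnf, -0.48 to 0.163 for Fos, -0.303 to 0.03 for Drd1 and -0.197 to 0.112 for Egr1. Between workers and controls they ran from -0.018 to 0.154 for Drd2, -0.113 to 0.048 for Htr2a and -0.023 to 0.136 for Fkbp5, and between parasites and controls from -0.207 to 0.127 for Drd1.

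With the replicate numbers as a block, the counts of genes were 0 between workers and parasites, 12 between workers and controls and 20 between parasites and controls with both numbers of the title, and 0, 5 and 19 with the first number. Shared calls were 9 and 4. Across groups, same-numbered libraries had residual correlations over genes from -0.078 to 0.217. Only 4 of 12 pairs were above 0.1 (3 of the 4 pairs of controls and workers). The model without a block was set in advance, because the labels do not say what the numbers mark. The own number was the best match in 12 of 24 cases, where chance gives 6, a hint from the data, not the design, that libraries of a number share something. Read depth is not known in counts, so how far it limits low genes could not be given.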

Other observations

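Clock genes differed from the home-cage controls in both directions. As a list they had no common direction (camera adjusted p = 0.707 for workers and 0.53 for parasites), but fry's test for changes in either direction gave an adjusted p of 2.7e-06 and 9.16e-06. The clock-controlled transcription factor gene Dbp was at 157 ± 10.6 FPKM in workers and 146 ± 21.8 in parasites against 113 ± 5.87 in controls (SD, n = 4), and the clock repressor Nr1d1 at 87.4 ± 5.07 and 85.1 ± 8.19 against 68.8 ± 3.58. The log2 difference from the controls was -0.34 in workers and -0.31 in parasites for the clock activator Arntl, and -0.78 and -0.84 for Nfil3, which was chosen after its values were seen. Adjusted over the list alone, 3 clock genes were higher and 2 lower in workers, and 3 higher and 3 lower in parasites, with 0 over all genes tested.

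A candidate explanation is that the tested rats were at another phase of the clock than the controls. It was tested on 8 clock genes whose values had not been looked at, of which Per3, Tef, Hlf, Nr1d2 and Bhlhe41 were predicted above the controls and Arntl, Npas2 and Cry1 below them. In workers 5 of the 8 and in parasites 6 of the 8 lay on the predicted side, and the bound set in advance was 6 in both, which parasites met and workers missed by 1 gene. Those on the other side in workers were Hlf (-0.15 ± 0.064, SE), Npas2 (0.11 ± 0.06) and Cry1 (0.02 ± 0.11), the last within its error. By the bound as written the test counts against a phase difference. Per3 (0.08 ± 0.086) and Nr1d2 (0.012 ± 0.09), on the predicted side in workers, also lay within their errors. Beyond 1 SE, 3 genes were on the predicted side and 2 on the other in workers, and 5 and 0 in parasites, so with these errors, looked at only after the result was seen, the count does not decide. A score of the 12 clock genes (8 of them predicted above the controls minus 4 below) was above the controls by 0.451 in workers and 0.541 in parasites (SD 0.181, 0.175 and 0.064 in controls, n = 4, exact permutation p = 0.0286 each), but the values of 4 of the 12 (Dbp, Nr1d1, Ciart and Nfil3) had been seen before. Within each set of titles it was above by 0.311 to 0.713, and as the sets are balanced over the groups this does not test their part.

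The libraries also differed by the first number of their titles, whose meaning the labels do not give. With the group means in the model, 9 of 12955 genes passed in limma by that number (1631 at an unadjusted p under 0.05), and only the real split, 1 of 100 drawn that part each group 2 and 2, gave that many, with a highest other count of 1. Named after their values were seen, the activity genes Btg2 (-1.88 ± 0.22, SE), Npas4 (-1.72 ± 0.22), Dusp1 (-1.32 ± 0.17), Junb (-1.04 ± 0.15) and Ier2 (-1.0 ± 0.16) and the stress gene Ppp1r15a (-0.66 ± 0.097) were lower, and the clock gene Per2 (0.44 ± 0.054), Bdh1 (0.25 ± 0.038) and LOC100361913 (1.13 ± 0.17) higher, in libraries whose title begins with 2. Of the 34 immediate-early genes 22 were lower there. The mean of that list differed between the sets by -0.17 in controls, -0.30 in parasites and -0.56 in workers.

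Chd9, AABR06058583.1 and LOC100360856 were chosen after their values were seen. The deposited values of Chd9 are of doubtful meaning as a level: they were 14.2 FPKM in parasite replicate 1-1 and 16.7 in worker replicate 2-1, and between 4570 and 13400 in the other libraries. Near LOC100912852 on chromosome 9, AABR06058583.1 (from 11296596) was at 131 ± 13.5 FPKM in parasites against 87.3 ± 8.11 in controls and 89.0 ± 11 in workers, and LOC100360856, farther off on that chromosome, at 73.5 ± 11.5 against 49.0 ± 3.49 and 51.2 ± 1.82.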
